A study of Rattus norvegicus with 12 samples.

How the data were processed

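Whole lungs of Sprague-Dawley rat pups were measured at postnatal days 4, 10 and 21 on 12 one-colour Cy3 NimbleGen arrays. Per the labels, 14 pups were growth restricted before birth (IUGR) through a low protein diet and 15 were controls. RNA was pooled from 2 or 3 pups per array, per the series design text, which left 2 arrays for each of the 6 combinations of diet and day. The deposited values are intensity on a linear scale, 1 per feature, and RMA is the only step that the submitters' processing notes name, without a version. Probe design, background settings and scan order are not recorded.

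The deposited table holds 26208 features, of which 10097 carry NM accessions and 16111 XM accessions. The 8 arrays of days 4 and 10 lay in register: each array's log2 values correlated with the mean of the others at 0.986 to 0.996 over all features, and their lowest intensities were 113 to 122. The day 21 arrays had been normalised apart from these 8, since their lowest intensities were 5.65 to 6.02 on 3 arrays and 148 on the other. On those 3 arrays the NM features correlated with the mean of days 4 and 10 at 0.946 to 0.948, whereas the XM features were out of register by 28 places and were left out. Control day 21 replicate 2 held values that correlated with that mean at 0.0197 and with its own next value at 0.593. They looked like single probes, 3 per feature, that had not been summarised, so this array was left out of the tests and entered only the alternatives that rebuilt it or used the table as filed. Array precision was limited by the number of arrays.

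Gene names came from RefSeq accessions matched without versions to the rat gene table of assembly GRCr8. A total of 9731 features matched 1 symbol each (9621 genes, 92 of them with more than 1 feature) and 16477 matched none. Gene positions were used only to find which genes neighbour each other.

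All values were analysed as log2 intensity with no further normalisation. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), with Benjamini-Hochberg adjustment over all features and an adjusted p threshold of 0.05. The 8 arrays of days 4 and 10 were fitted together with 1 mean per group (4 residual degrees of freedom, prior 3.79). This fit gave IUGR minus control at day 4, at day 10 and averaged over both, the difference between both effects, and day 10 minus day 4 in controls. Day 21 was fitted apart, on the NM features of 2 IUGR arrays and 1 control array, so the spread came from the IUGR arrays alone (1 residual degree of freedom). The plan made before the data were examined had 1 fit of all 12 arrays, an average over 3 days, a test across 3 days and a day 21 minus day 10 comparison. The register problems ruled out that fit, and the average and the test across 3 days were run only as alternatives, on the NM features of 11 arrays and on the table as filed. Day 21 minus day 10 was not computed because age and processing cannot be told apart there. The gene lists, the rule for named genes and most alternatives belong to that plan.

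Of 41 gene lists with 743 members, 521 members were measured, and 37 lists had at least 5. The lists of B lymphocyte, basement membrane, thymus and sex chromosome genes had too few. Lists were tested with camera (limma, preset correlation 0.01, 1 feature per gene, the one with the highest mean), adjusted over the 37 lists, with an estimated correlation, ranks and fry as alternatives. Named genes were, for each comparison, the 12 highest and 12 lowest past the threshold. Where fewer than 10 passed, they were those that passed plus the 6 higher and the 6 lower with the smallest p. The rule added up to 4 members with the smallest p from each list past its threshold and a fixed panel of lung genes, of which Lox and Mki67 were not measured. A few genes that the rule takes are not reported here. The fat and heart genes shown per array came from these lists and were picked after their values were seen.

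A developmental score was the slope of each array's deviation from its own day's mean on the change between the other days, over 10097 features. IUGR and control scores were compared with exact two-sided permutation tests within days.

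The tests were tried on simulated data with the real group sizes, in which genes were drawn independently of each other. Such data cannot show how often a list test makes false calls where genes vary together. For day 4, limma recovered 85 of 100 features changed by a log2 of 1 and 97 of 100 changed by 2, with 15 false calls among 26208. For day 21 it recovered 0 of 100 at each size past the adjusted threshold, and 78 and 99 at an unadjusted p of 0.05, among 10097. A list shifted by -0.4 at day 4 had an adjusted p of 5.14e-12 with the preset and 0.0686 with an estimated correlation over 9621 genes. At day 21 those values were 0.178 and 0.986 over 9496 genes.

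Alternatives covered quantile normalisation, median centring, removal of the dimmest 30% of features, each array left out in turn, the replicate number as a block, array weights, an intensity trend with a robust prior, only the compared groups, genes in place of features and a 1.5-fold limit. Alternatives added after the data were seen covered the whole table as filed, a fit of the 11 arrays in register, the XM features moved by 28, the unsummarised array rebuilt from blocks of 3 (8554 features, quantiles set to those of the other day 21 arrays), NM features only, and removal of 2 IUGR arrays high in heart and brown fat genes. Scripts ran in Python 3.11.15 (pandas 2.3.3, numpy 2.4.6, matplotlib 3.10.9) and R with statmod 1.5.0.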

Results

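Gene expression in rat lung was compared between IUGR pups, whose growth was restricted before birth by a low protein diet, and control pups over the days in which alveoli form. Each of the 6 groups (IUGR and control at days 4, 10 and 21) had 2 arrays, each of a pool of 2 or 3 pups. The p-values of single features below measure spread between pools, which the labels give as separate samples. Those of gene lists come from camera, which compares a list's genes with the other genes, and mainly reflect spread between genes. The pups and litters in each pool are not given, so pools may share litters. Median intensity was 411 to 418 on the 8 arrays of days 4 and 10, and 270.1 to 278 on the 3 usable arrays of day 21. Differences are log2 values, IUGR minus control unless stated, followed by the standard error where one is given. Of the 37 gene lists tested, 18 passed in at least 1 of the comparisons of IUGR with control and 19 in none. None passed with an estimated correlation in any comparison (adjusted p = 0.160 or more with an estimated correlation), and the mast cell and glucocorticoid lists passed only at day 21, with its 1 control pool.

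Genes of brown fat and heart muscle differed strongly between single arrays. Ucp1, the heat-producing uncoupling protein of brown fat, had a log2 intensity of 12.02 on IUGR day 4 replicate 2 and 7.91 on replicate 1, against at most 8.79 in the controls. At day 10 it was 13.29 and 11.30 in IUGR against 7.71 and 9.15, and at day 21 it was 13.24 in the control and 6.12 and 6.60 in IUGR. Nppa, the atrial natriuretic peptide of heart muscle, was 12.08 on IUGR day 4 replicate 2, 10.74 on IUGR day 10 replicate 2 and 13.51 on IUGR day 21 replicate 2. The other arrays held Nppa at 5.67 to 10.04.

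**Figure D1:**
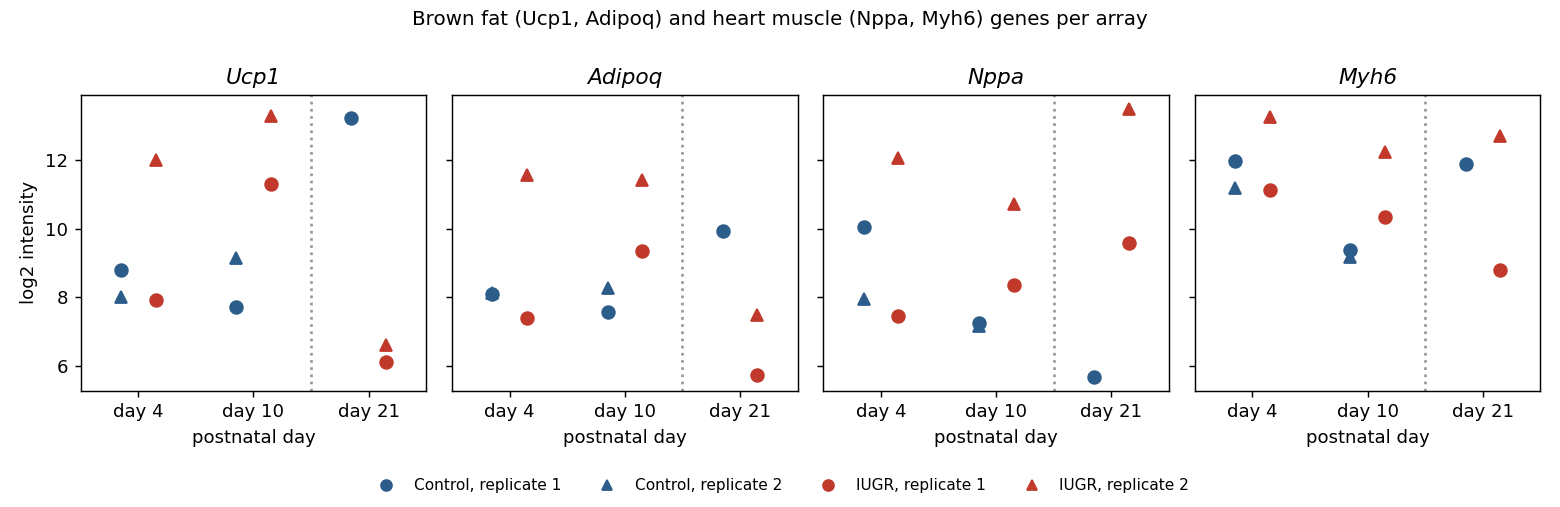
Log2 intensity (y axis) of brown fat genes (Ucp1, Adipoq) and heart muscle genes (Nppa, Myh6) on each array by postnatal day (x axis), with circles for replicate 1 and triangles for replicate 2. The dotted line parts day 21, which was normalised separately. IUGR replicate 2 was the highest array for all 4 genes at days 4 and 10.

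Day 4 asked what growth restriction changes early in alveolar formation. Interferon-induced genes were lower in IUGR lungs, with a list mean of -0.30 over 20 genes, 16 of them lower (adjusted p = 1.82e-08; adjusted p = 0.160 with an estimated correlation). Their deviation from the 8-array mean was -0.03 and -0.01 in IUGR pools and 0.35 and 0.21 in controls. Inflammatory cytokine and adhesion genes were higher, with a mean of 0.20 and 15 of 18 genes higher (adjusted p = 0.00107; adjusted p = 0.579 with an estimated correlation). Lists of 3 more kinds also shifted: red cell genes fell (mean -0.29, adjusted p = 0.00393), as did neutrophil genes (-0.19, adjusted p = 0.0367), and cholesterol synthesis genes rose (0.11, adjusted p = 0.0277). With an estimated correlation their adjusted p-values were 0.687, 0.680 and 0.687.

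Among interferon genes, the antiviral enzyme Oas1a was -0.72 ± 0.11, the ubiquitin-like protease Usp18 -0.55 ± 0.11, Mx2 -0.79 ± 0.16 and Rsad2, an antiviral enzyme, -0.82 ± 0.18 (n = 2 and 2). None of the 20 passed over all features, while 9 lower and 1 higher passed adjusted over the list alone. In the inflammatory list, the chemokines Cxcl1 and Ccl2 were 0.78 ± 0.13 and 0.53 ± 0.13, the cytokine Il1b was 0.58 ± 0.11 and Cxcl2 was 0.35 ± 0.10, with 4 higher adjusted over the list alone. Other genes with the smallest p were lower for Pde6h (-0.89 ± 0.10), Stfa2l1 (-0.95 ± 0.11), the death ligand Tnfsf10 (-0.85 ± 0.11) and the MHC class I genes RT1-S3 (-0.66 ± 0.09) and RT1-A1 (-1.30 ± 0.19). They were higher for Spata1 (0.53 ± 0.08), the macrophage elastase Mmp12 (1.38 ± 0.23), Gng5 (0.48 ± 0.08) and Corin (0.51 ± 0.09). Their adjusted p-values were 0.0930 to 0.267. In red cell genes Rhag was -0.56 ± 0.22 and Hemgn -0.59 ± 0.27, in neutrophil genes Mmp8 was -0.72 ± 0.19 and S100a8 -0.39 ± 0.13, and Msmo1 of cholesterol synthesis was 0.30 ± 0.14. Of the red cell, neutrophil and cholesterol synthesis genes, 0, 1 and 0 passed adjusted over the list alone. Of the surfactant and elastin genes of the panel none passed, with Sftpc at 0.04 ± 0.08, Sftpb at 0.10 ± 0.10 and Eln at 0.25 ± 0.08.

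Respiratory chain genes (0.12, adjusted p = 0.00678), MHC class II genes (-0.13, adjusted p = 0.0277) and endothelial genes (-0.08, adjusted p = 0.0408) also shifted, with 24 of 27 genes higher, 10 of 12 lower and 12 of 15 lower and adjusted p = 0.687, 0.579 and 0.687 with an estimated correlation. Atp5mc1, RT1-Db1 and Aplnr had the smallest p in these lists at 0.24 ± 0.08, -0.38 ± 0.15 and -0.31 ± 0.10, and 0 members of each passed adjusted over the list alone. No feature passed limma's adjusted threshold at day 4, against 2514 at an unadjusted p of 0.05, where chance gives 1310.4 of 26208. Without IUGR day 4 replicate 1, 644 features passed, and without replicate 2, 89 passed. Without IUGR day 4 replicate 2, the array high in heart and brown fat genes, red cell (-0.06), respiratory chain (0.03), MHC class II (-0.05), neutrophil (-0.12) and endothelial (-0.04) genes no longer passed. Cholesterol synthesis no longer passed without IUGR replicate 1 (0.05), control replicate 1 (0.11) or control replicate 2 (0.11), and the inflammatory list no longer passed without IUGR replicate 1 (0.14, adjusted p = 0.0631). Neutrophil genes were also not past without control replicate 1 (-0.18) or 2 (-0.20), nor were MHC class II (-0.11) and endothelial genes (-0.06) without control replicate 2.

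**Figure D2:**
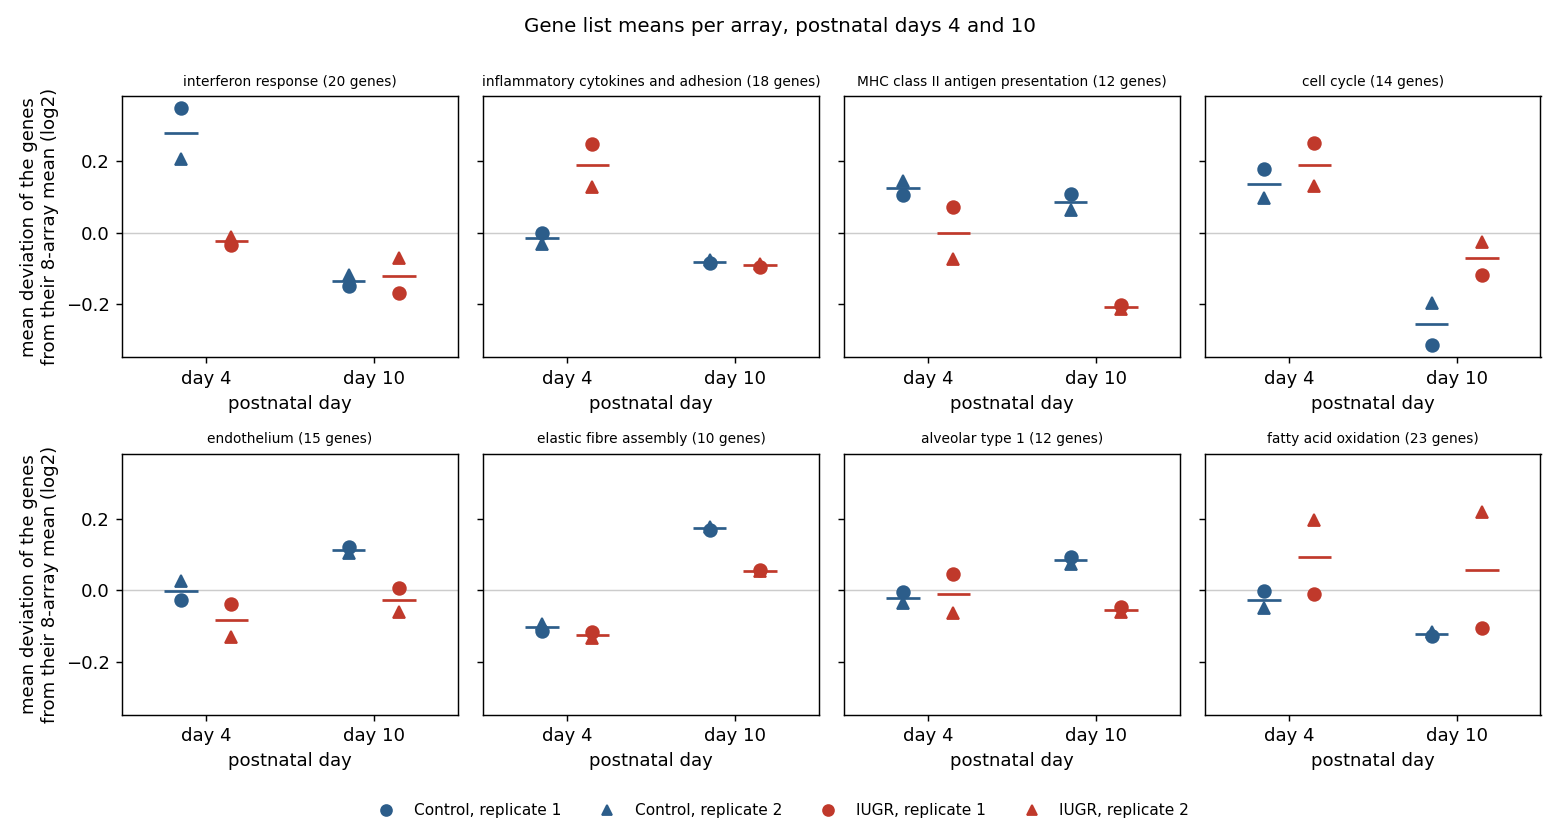
Mean deviation of each list's genes from their mean over 8 arrays (log2, y axis) at days 4 and 10 (x axis), with 1 point per array and bars at group means. Interferon genes stood at 0.35 and 0.21 in control lungs at day 4, above all other arrays, and MHC class II genes were -0.20 and -0.21 in IUGR lungs at day 10.

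At day 10, cell cycle genes were higher in IUGR lungs and MHC class II genes were lower. The cell cycle list rose by a mean of 0.18, with 13 of 14 genes higher (adjusted p = 1.38e-05; adjusted p = 0.569 with an estimated correlation). MHC class II genes fell by a mean of 0.29, with 10 of 12 lower (adjusted p = 0.000112; adjusted p = 0.404 with an estimated correlation). Endothelial (-0.14, adjusted p = 0.00455), elastic fibre (-0.12, adjusted p = 0.0158) and alveolar type 1 cell genes (-0.14, adjusted p = 0.0317) fell, in 13 of 15, 8 of 10 and 9 of 12 genes, with adjusted p = 0.634, 0.569 and 0.569 with an estimated correlation. Heart muscle (1.02, adjusted p = 0.000133) and adipose tissue genes (1.14, adjusted p = 0.00455) rose, with adjusted p = 0.634 and 0.569 with an estimated correlation.

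RT1-Da, RT1-Bb, RT1-Ba and RT1-Db1, the chains that present antigen to T cells, were -0.62 ± 0.09, -0.85 ± 0.12, -0.53 ± 0.08 and -0.78 ± 0.15 (n = 2 and 2). None of the 12 passed over all features and 5 lower passed adjusted over the list alone. In cell cycle genes the thymidylate synthase Tyms was 0.42 ± 0.09, cyclin Ccnb1 0.30 ± 0.09, Cdc20 0.28 ± 0.10 and Cdk1 0.29 ± 0.11, with 1 higher adjusted over the list alone. In the lists that fell, Ager of alveolar type 1 cells was -0.40 ± 0.09, the water channel Aqp5 -0.27 ± 0.08, the junction protein Cldn5 -0.33 ± 0.09, Pecam1 -0.30 ± 0.09, Loxl1 -0.22 ± 0.07 and Eln -0.17 ± 0.08. Adjusted over the list alone, 1 alveolar type 1 gene, 0 endothelial and 0 elastic fibre genes passed. Other genes with the smallest p were the protease Prss12 (0.80 ± 0.10), Alb (0.50 ± 0.07), Dctd (0.64 ± 0.12), the hyaluronan synthase Has2 (0.50 ± 0.10) and Plet1 (0.50 ± 0.10). On the lower side were Saa4 (-0.60 ± 0.08), Slc6a20a (-0.57 ± 0.09), Fgr (-0.55 ± 0.08) and Laptm5 (-0.58 ± 0.09), with adjusted p-values of 0.303 to 0.364 over both directions.

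Lipid and respiratory chain lists also passed. Fatty acid oxidation (0.18, adjusted p = 0.00714), respiratory chain (0.08, adjusted p = 0.00621), lipofibroblast and PPARG lipid (0.40, adjusted p = 0.0119) and skeletal muscle genes (0.23, adjusted p = 0.0317) rose, with adjusted p = 0.634, 0.665, 0.634 and 0.634 with an estimated correlation. IUGR replicate 2 held the highest Ucp1, Adipoq and Myh6 levels of the day, and the mean fatty acid oxidation deviation was 0.22 on that array, against -0.11 on replicate 1 and -0.13 and -0.12 in the controls. Fabp4, a fatty acid carrier of fat cells, was 2.64 ± 0.76, Acadl 0.49 ± 0.19 and the heart troponin Tnnt2 1.75 ± 0.46. Adjusted over the list alone, 2 heart genes were higher, 2 lipofibroblast genes higher and 2 lower, and 0 passed in each of the adipose, fatty acid oxidation, respiratory chain and skeletal muscle lists. Without that array, fatty acid oxidation was 0.02, respiratory chain -0.04, lipofibroblast 0.16, skeletal muscle 0.07, adipose 0.70, endothelial -0.11, alveolar type 1 -0.13 and elastic fibre genes -0.12, none past the threshold. The cell cycle, MHC class II and heart lists passed with each array of days 4 and 10 left out in turn, though the heart mean was 0.49 without IUGR replicate 2. Elastic fibre (-0.11) and lipofibroblast (0.36) genes also did not pass without control replicate 2, nor alveolar type 1 (-0.13) and skeletal muscle genes (0.18) without control replicate 1. No feature passed limma's adjusted threshold, against 2095 at an unadjusted p of 0.05 of 26208 and 2 past the adjusted threshold without IUGR replicate 1.

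Averaged over days 4 and 10, the comparison took the mean of both effects, with 4 IUGR and 4 control arrays. In it 11 lists passed, and 7 of 18 splits of the arrays within days gave as many or more, the real one included. An average need not be shared by both ages, since interferon genes were -0.30 at day 4 and 0.01 at day 10, and cell cycle genes were 0.05 (adjusted p = 0.377) and 0.18. MHC class II genes were lower (-0.21, 11 of 12 lower, adjusted p = 1.95e-05; adjusted p = 0.281 with an estimated correlation), as were interferon genes (-0.14, 16 of 20 lower, adjusted p = 0.000302; adjusted p = 0.328 with an estimated correlation). Cell cycle genes were higher (0.12, 12 of 14 higher, adjusted p = 0.000412; adjusted p = 0.475 with an estimated correlation). C6, a terminal complement component, was lower in IUGR at days 4 and 10, with a mean of -1.41 ± 0.17, from 10.29 and 10.02 against 11.15 and 11.78 at day 4, and 11.16 and 10.74 against 12.27 and 12.65 at day 10. At day 21 it was the other way, at 10.42 and 10.42 against 9.06 in the control. The adjusted p of its average over days 4 and 10 was 0.308, so it did not pass.

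The chemokine receptor Cxcr4 was -0.39 ± 0.06, the interferon gene Ifi27 -0.34 ± 0.05, Ifit3 -0.42 ± 0.10 and the endocytic receptor Lrp2 -0.36 ± 0.06, while Bloc1s2 was 0.50 ± 0.08, the adhesion genes Cntn3 and Cdh6 were 0.60 ± 0.10 and 0.35 ± 0.06, Aoc1 was 0.43 ± 0.08 and the kinetochore gene Spc25 was 0.34 ± 0.07. Adjusted over the list alone, 5 MHC class II genes were lower, 7 interferon genes lower and 1 higher, and 1 cell cycle gene higher, beside 1 heart gene higher, 3 lipofibroblast genes higher and 1 lower, and 0 in each of the other lists past the threshold. Endothelial genes fell (-0.11, adjusted p = 0.000494), inflammatory genes rose (0.10, adjusted p = 0.00905) and respiratory chain (0.10), heart (0.73), skeletal muscle (0.31), adipose (0.82), fatty acid oxidation (0.15) and lipofibroblast genes (0.29) rose, with adjusted p-values of 0.000286 to 0.0288 and, with an estimated correlation, adjusted p = 0.475 to 0.562 over these 8 lists. Without the 2 IUGR arrays high in heart and brown fat genes, MHC class II genes were -0.17 and interferon genes -0.17. Cell cycle genes were then 0.13 and inflammatory genes 0.12. Endothelial genes were -0.07, fatty acid oxidation 0.02, lipofibroblast 0.08, heart 0.11, adipose 0.22, respiratory chain -0.00444 and skeletal muscle genes -0.00973. That left 1 IUGR pool at each day, so the spread came from the control pools alone. This removal did not clear all signal of heart and brown fat genes. IUGR day 10 replicate 1, which stayed, had Ucp1 at 11.30 against 7.71 and 9.15 in controls. At day 10 heart (0.49) and adipose genes (0.70) remained higher. On IUGR day 4 replicate 1, Ucp1 was 7.91, below both controls of that day. Without IUGR day 4 replicate 2 alone, heart (0.37), skeletal muscle (0.07), adipose (0.44), fatty acid oxidation (0.10), respiratory chain (0.06) and lipofibroblast genes (0.20) did not pass. Without IUGR day 10 replicate 2, respiratory chain (0.04), fatty acid oxidation (0.07), adipose (0.60), skeletal muscle (0.23) and lipofibroblast genes (0.18) did not pass. The lipofibroblast list also did not pass without control day 10 replicate 2 (0.28), nor the inflammatory list without IUGR day 4 replicate 1 (0.07). No feature passed in limma, against 2689 at an unadjusted p of 0.05 of 26208, while 166 passed without IUGR day 4 replicate 1, 49 without IUGR day 4 replicate 2 and 1 without control day 4 replicate 1. Panel genes gave Igf1, a growth factor, at -0.19 ± 0.08, Fbln5 at -0.11 ± 0.05, Vegfa at 0.01 ± 0.07 (0.22 ± 0.10 at day 4 and -0.19 ± 0.10 at day 10) and Pparg at 0.04 ± 0.13, none past.

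The difference between both effects (day 10 effect minus day 4 effect) asked whether the response depends on age. Interferon genes had the smallest p, with a difference of 0.31 and 17 of 20 members higher (adjusted p = 1.29e-05; adjusted p = 0.328 with an estimated correlation). The same 2 control pools of day 4 enter this difference, the day 4 effect and the change in controls, so these results are not independent of each other. Inflammatory genes differed by -0.21 (adjusted p = 0.0164) and monocyte and macrophage genes by -0.16 (adjusted p = 0.0318), each with adjusted p = 0.624 with an estimated correlation. Red cell (0.34, adjusted p = 0.00785), neutrophil (0.26, adjusted p = 0.0333) and cell cycle genes (0.13, adjusted p = 0.0164) differed the other way, also with adjusted p = 0.624 with an estimated correlation.

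Oas1a differed by 0.81 ± 0.16, Usp18 by 0.76 ± 0.16 and Mx2 by 0.87 ± 0.23, and 3 interferon genes were higher adjusted over the list alone. Il1b and Cxcl1 differed by -0.77 ± 0.16 and -0.85 ± 0.18, with 4 lower adjusted over the list alone, Mmp8 of neutrophils by 1.09 ± 0.26, with 1 neutrophil gene higher adjusted over the list alone, the macrophage gene Cd68 by -0.32 ± 0.13, and the cyclin Ccnb1 by 0.41 ± 0.13. None of the monocyte, cell cycle and red cell genes passed adjusted over the list alone. Eln was 0.25 ± 0.08 at day 4 and -0.17 ± 0.08 at day 10, a difference of -0.42 ± 0.11 (adjusted p = 0.504). Alb (0.87 ± 0.11), Plet1 (0.94 ± 0.14) and Nlgn1 (1.13 ± 0.20) were highest and Lst1 (-0.87 ± 0.12), Unc119 (-0.75 ± 0.12) and Flii (-0.77 ± 0.14) lowest by smallest p. No feature passed in limma, against 1933 at an unadjusted p of 0.05 of 26208. Without IUGR day 4 replicate 1, 152 passed, without IUGR day 4 replicate 2, 36 passed, and without control day 4 replicate 1, 1 passed. Without IUGR day 4 replicate 2, cell cycle (0.07), monocyte (-0.16), neutrophil (0.19) and red cell lists (0.11) did not pass, and without control day 4 replicate 1 neither did cell cycle (0.09), monocyte (-0.15) or neutrophil (0.25). Without IUGR day 10 replicate 2, cell cycle (0.08), monocyte (-0.13), neutrophil (0.18) and inflammatory lists (-0.22) did not pass. Without IUGR day 4 replicate 1 the inflammatory (-0.16) and monocyte lists (-0.16) did not, without control day 10 replicate 1 the cell cycle list (0.07) did not, and the neutrophil list also did not without control day 4 replicate 2 (0.28) or control day 10 replicate 2 (0.23).

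The control lungs of days 4 and 10 gave the change over this period without growth restriction. Elastic fibre genes rose as cell cycle, neutrophil, interferon and red cell genes fell, with adjusted p = 0.162 to 0.432 with an estimated correlation. Eln, the elastin gene, rose by 0.96 ± 0.08 (1.95-fold, n = 2 and 2, adjusted p = 0.00424), and Ltbp2 and Efemp1 of the same list rose by 0.49 ± 0.08 and 0.49 ± 0.09. The neutrophil genes Np4, S100a8, Mmp8 and S100a9 fell, with differences of -1.98 ± 0.11, -1.71 ± 0.13, -1.63 ± 0.19 and -1.61 ± 0.17. Apoe, the lipid carrier, rose by 1.16 ± 0.10, and Dlk1, an imprinted growth gene, fell by 1.31 ± 0.08.

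By list, elastic fibre genes rose by a mean of 0.28 with 9 of 10 higher (adjusted p = 4.46e-05), while cell cycle (-0.39, 14 of 14 lower, adjusted p = 1.63e-06), neutrophil (-0.96, 9 of 9, adjusted p = 3.68e-06), interferon (-0.41, 17 of 20, adjusted p = 4.38e-05) and red cell genes (-0.67, 10 of 10, adjusted p = 0.000160) fell. With an estimated correlation their adjusted p-values were 0.162, 0.299, 0.162, 0.162 and 0.432. Over all features 3 of 10, 4 of 14, 4 of 9, 5 of 20 and 3 of 10 members passed, and adjusted over the list alone 5, 11, 6, 7 and 7 passed. Oas1a (-1.05 ± 0.11), Ccnb1 (-0.73 ± 0.09) and the red cell membrane gene Rhag (-1.54 ± 0.22) fell. Heart muscle (-1.09), respiratory chain (-0.17), surfactant and alveolar type 2 (-0.21), cholesterol synthesis (-0.17), antioxidant (-0.16) and mesothelial genes (-0.29) fell, and endothelial (0.11), alveolar type 1 (0.10) and interstitial collagen genes (0.12) rose. Adjusted p-values of these 9 lists were 0.0122 to 0.0478, and with an estimated correlation adjusted p = 0.299 to 0.768. Adjusted over the list alone, 4 heart, 6 antioxidant and 2 mesothelial genes were lower, 4 alveolar type 2 genes lower and 1 higher, 1 alveolar type 1 gene higher, and 0 passed in each of the other 4 lists. Napsa of alveolar type 2 cells (-0.49 ± 0.08), Gpx1 of antioxidant defence (-0.62 ± 0.10) and Tnnt2 of heart (-2.42 ± 0.46) fell. The source of the heart muscle genes was not tested, nor whether its share of the control pools differed between the days. Nppa was 10.04 and 7.94 in the controls of day 4 and 7.24 and 7.17 in those of day 10. The olfactory receptors Or14j3d, Or14j3b and Or6c69 rose by 0.92 to 1.26. Whether sequence differences between the pups of days 4 and 10 contribute to this rise was not tested. Other genes among the highest were Clic2, Cyp2b12, Mstn, Usp19, Ceacam1, Nell1 and C5h1orf174 (1.23 to 0.87), and among the lowest RatNP-3b, Csta3, Stfa2l1 and Ces1e (-1.82 to -1.38).

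In all, 1123 features passed limma's adjusted threshold, 601 higher and 522 lower, of 26208 tested and with 5538 at an unadjusted p of 0.05. Among features with a gene name 120 rose and 229 fell. The count depended on single control pools, at 7 without control day 4 replicate 1, 146 without control day 4 replicate 2, 30 without control day 10 replicate 1 and 14 without control day 10 replicate 2, and it was 2264 without either IUGR day 4 array. Without control day 4 replicate 1, interstitial collagen (0.11), endothelial (0.09), antioxidant (-0.14), heart (-0.87) and mesothelial lists (-0.25) did not pass. Interstitial collagen also did not pass without control day 4 replicate 2 (0.13) or control day 10 replicate 2 (0.09), alveolar type 1 (0.09) and cholesterol synthesis (-0.17) did not without control day 4 replicate 2, and mesothelial genes (-0.23) did not without control day 10 replicate 2. Antioxidant (-0.14), alveolar type 1 (0.09) and cholesterol synthesis (-0.14) did not without control day 10 replicate 1. With the dimmest 30% of features left out, 6 of the 14 lists passed.

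**Figure D3:**
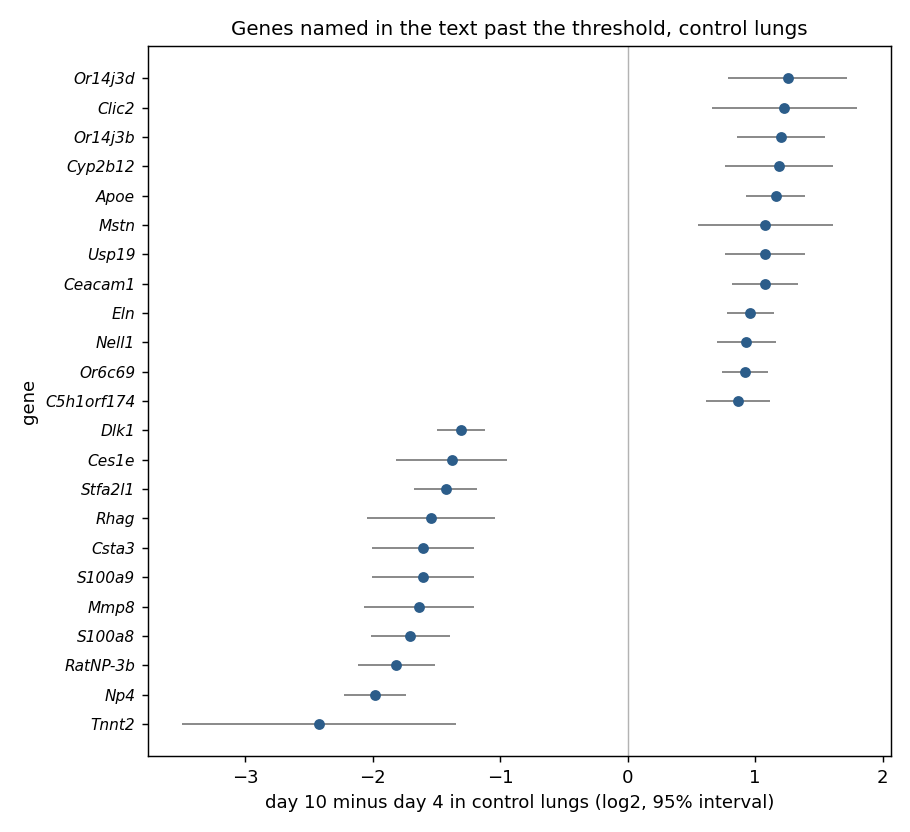
Day 10 minus day 4 in control lungs (log2, x axis) for the genes named in the text from the highest and the lowest past the threshold (y axis), with 95% intervals. Eln rose by 0.96 and Tnnt2 fell by 2.42.

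At day 21, fat genes were lower in the 2 IUGR pools than in the single usable control pool. The p-values of single features there take their spread from the IUGR pools alone. They and the list p-values rest on 1 control pool, and a feature of that pool alone would look the same as a diet effect. Ucp1 fell by 6.88 ± 0.29 (adjusted p = 0.0392), from 13.24 in the control to 6.36 ± 0.34 (SD, n = 2). The adipose tissue list fell by a mean of 2.11, with 6 of 7 genes lower (adjusted p = 1.19e-08), as did the lipofibroblast list (-0.58, 11 of 12 lower, adjusted p = 0.000486), fatty acid oxidation (-0.40, 19 of 23, adjusted p = 0.000486) and mast cell genes (-0.74, 7 of 9, adjusted p = 0.000163). Glucocorticoid response genes rose by 0.30 (13 of 16 higher, adjusted p = 0.00192). With an estimated correlation all 5 had adjusted p = 0.998.

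Fabp4 was -3.25 ± 0.27, the fat droplet gene Cidec -2.53 ± 0.23, Adipoq -3.34 ± 0.73, the mitochondrial carnitine enzyme Cpt1b -2.49 ± 0.32 and the mast cell protease Mcpt1 -1.88 ± 0.29. Among glucocorticoid genes Zbtb16 was 0.83 ± 0.25 and Fkbp5 0.73 ± 0.23. Adjusted over the list alone, 4 adipose, 3 mast cell, 1 lipofibroblast, 2 fatty acid oxidation and 0 glucocorticoid genes passed. The macrophage receptor Vsig4 (-3.52 ± 0.22), Or14j10b (-3.57 ± 0.24), Thrsp (-3.27 ± 0.22) and Pck1 (-2.57 ± 0.23) were lower. Klkb1 (4.24 ± 0.33), Abcg3l4 (2.05 ± 0.23), Ppef1 (1.94 ± 0.22), Impg1 (2.01 ± 0.23), Fam107a (1.88 ± 0.24) and Pcdhgc3 (1.69 ± 0.23) were higher. None of these passed the adjusted threshold. Klkb1 was 7.93 and 7.33 in the IUGR pools and 3.38 in the control, near the low end of that array. Of the panel genes, Sftpc was 0.02 ± 0.23, Eln -0.10 ± 0.23 and Pparg -0.71 ± 0.39, none past the threshold. Ucp1 was the only feature past the adjusted threshold of 10097, with 551 at an unadjusted p of 0.05, and its adjusted p was 0.188 after quantile normalisation and 0.213 after median centring. The rebuilt control pool, put on the scale of the other day 21 arrays by quantiles, again gives an arm of 1 array when it takes the place of the other. There 45 features were higher and 210 lower of 8554, Ucp1 was -2.21 (adjusted p = 0.0330), adipose genes were -0.81 and 0 of the 5 lists passed. With it added, Ucp1 was -4.55 and did not pass (adjusted p = 0.930).

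The developmental score asked where IUGR lungs lay, against controls, along the change between the other days, taken over both diets. For days 4 and 10 that change runs to day 21, which was normalised separately, so age and processing cannot be told apart in it. The scores of days 4 and 10 and the average therefore cannot decide whether IUGR lungs lagged in development. IUGR minus control was -0.00706 at day 4 (exact permutation p = 0.667), -0.0133 at day 10 (exact permutation p = 0.333) and -0.128 at day 21 (exact permutation p = 0.667). The smallest p these designs allow is 0.333. Averaged over days it was -0.0493 (exact permutation p = 0.352 over 108 assignments, smallest possible 0.00926). The pooled spread between replicates, 0.0730 (SD), came mostly from the IUGR arrays of day 21, at -0.158 and 0.0728. Replicates of days 4 and 10 differed by 0.000405 to 0.00765, and at day 10 both IUGR arrays lay below both controls. IUGR minus control at days 4 and 10 was more negative with quantile normalisation and without the dimmest features. In simulated lungs set back by 0.1 the score found -0.0935. Without IUGR day 21 replicate 1 the average was -0.0100 (exact permutation p = 0.0278), the smallest p possible with the 72 assignments left, and day 21 then had 1 array per diet.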

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

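The tests of brown fat and heart tissue, of single arrays and of leukocyte content below were chosen only after the result was seen. So were the alternatives that rebuilt or moved values. Leaving out each array in turn was planned.

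The IUGR effect differed between days 4 and 10 for 6 gene lists, each by a test of the difference itself (day 10 effect minus day 4 effect). Interferon genes differed by 0.31, red cell genes by 0.34, neutrophil genes by 0.26, cell cycle genes by 0.13, inflammatory genes by -0.21 and monocyte and macrophage genes by -0.16. With an estimated correlation none of the 6 passed (adjusted p = 0.328 to 0.624), and all but the interferon list no longer passed with some single array left out. Values outside the main measurement also carried signal. After the XM features of day 21 were moved by 28 places, they correlated with days 4 and 10 at 0.945 (IUGR replicate 1), 0.939 (IUGR replicate 2) and 0.940 (control replicate 1). Features of control day 21 replicate 2 rebuilt from blocks of 3 values correlated with the other day 21 arrays at 0.959. The places of the blocks were chosen by their match to these same arrays, so part of this value was set by the rebuilding.

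Interferon genes were lower in IUGR lungs at day 4, though with an estimated correlation camera did not pass them (adjusted p = 0.160). A single odd array is argued against, since the difference nearest to 0 with 1 array left out was -0.229. Fewer leukocytes in the IUGR pools stay open, since of T lymphocyte and monocyte genes the lower difference was 0.119 with neither list past the threshold, while neutrophil (-0.19) and MHC class II genes (-0.13) passed and were lower, with adjusted p = 0.680 and 0.579 with an estimated correlation and not past without IUGR day 4 replicate 2 (-0.12 and -0.05). The diet and any other difference between the pups of both groups were not tested. A response to growth restriction may be behind it, as a hypothesis found on these arrays and not tested on others.

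Fat and heart genes moved with lipid and respiratory chain genes, and dissection and a diet effect on fat near the lung were not separated. At day 10, 20.9% of the mean difference of the fatty acid oxidation, respiratory chain and lipofibroblast lists was left without IUGR replicate 2, so most of it lay in that pool, which any cause particular to it would give. Brown fat and heart tissue may be that cause but are not decided, since over the other 7 arrays these lists correlated with heart and adipose genes within days at 0.931 (exact permutation p = 0.0556). These 7 arrays include IUGR day 4 replicate 2, itself high in heart and brown fat genes, and the correlation without it was not tested. A change of the whole diet group is not decided, because IUGR replicate 1 lay only 0.0375 above the higher control and is 1 array. At day 21 Ucp1 was -2.21 in IUGR against the rebuilt control pool and -6.88 against the other, so brown fat in control replicate 1 may account for much of the difference.

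Olfactory receptor features near RT1 (MHC) genes were frequent among the smallest p at days 10 and 21, and none was at day 4. Of these features, 8 of 99 (33 on each of 3 days) were among the 200 smallest p of their day, 0 at day 4, 2 at day 10 and 6 at day 21 with its single control pool, against 28 of 3266 elsewhere (3, 0 and 25 by day, odds ratio 10.1, Fisher's exact p = 6.48e-06). Sequence differences between the MHC haplotypes of outbred pups may therefore be a source at days 10 and 21. The RT1 genes named for days 4 and 10 belong to the same region, but the test gave no sign of this source at day 4. The features are not independent, and a diet effect on MHC class II genes stays open. This test was not run for the change from day 4 to day 10 in controls.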

How the results depend on the processing

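The alternatives that removed the 2 IUGR arrays, rebuilt or moved values, used all 12 columns or 11 arrays, or kept NM features only were chosen after the result was seen. The cause was not tested for any change below.

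Of the summary values, 230 kept their size or side, 73 moved and 1 became stronger; of the list values 898 kept their call, 220 lost it and 6 reversed, none of them past the threshold in the other direction; of the named genes 5400 kept it, 148 lost it, 147 gained it and 48, past in neither fit, changed sign. Respiratory chain genes at day 10 (0.08) ranged from -0.0424 to 0.211 with 1 array left out and were -0.0424 without the 2 IUGR arrays high in heart and brown fat genes. Averaged, leaving out these 2 arrays gave -0.00444 for respiratory chain (from 0.10) and -0.00973 for skeletal muscle genes (from 0.31). The rebuilt control in place at day 21 gave 0.0261 for lipofibroblast (from -0.58) and 0.0114 for fatty acid oxidation genes (from -0.40). With the correlation estimated, 0 lists passed in each of the 6 comparisons, and with fry 2 at day 4, 2 at day 10, 2 averaged, 2 for the difference, 8 for the control change and 0 at day 21, of which 1, 2, 1, 1, 5 and 0 were among the lists called. The inflammatory list at day 4 (adjusted p = 0.144) and the cell cycle list at day 10 (adjusted p = 0.234) were not. Of the 11 lists called at day 10, 10 passed with camera on ranks and 8 without the dimmest 30% of features. Leaving out the 2 IUGR arrays high in heart and brown fat genes gave 60 features at day 4, 29 averaged, 11 for the difference and 2997 for the control change, and 3, 4 and 4 lists at day 4, at day 10 and averaged. For the difference it gave 5 lists, only 2 of them among the 6, with interferon at 0.27 and inflammatory genes at -0.28 past, and cell cycle at 0.03 (from 0.13), neutrophil at 0.11 (from 0.26), red cell at 0.15 (from 0.34) and monocyte genes at -0.13 (from -0.16) not.

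With 1 array left out, which leaves an arm of 1 array assumed to vary like the others, features ranged from 0 to 644 at day 4, 0 to 2 at day 10, 0 to 166 averaged, 0 to 152 for the difference and 7 to 2264 for the control change. Lists ranged from 3 to 11, 3 to 16, 6 to 17, 3 to 14 and 10 to 18. Scores ranged from -0.0109 to -0.00324 at day 4, -0.0148 to -0.0111 at day 10, -0.243 to -0.0123 at day 21 and -0.0883 to -0.0100 averaged, the last with p = 0.0278 by exact permutation, the smallest possible with 1 array per diet at day 21.

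At day 21 the feature count of 1 became 0 with quantile normalisation, 0 with median centring, 2 without the dimmest 30%, 74 with an intensity trend and robust prior, 0 with the rebuilt control added, 255 (45 higher and 210 lower) with it in place of replicate 1, 579 in 1 fit of 11 arrays and 0 as filed. Its 5 lists became 10 with the trend and robust prior, 2 with the rebuilt control added and 0 with it in place. The control change of 1123 features became 3551 with array weights, 2997 with only the compared groups, 348 with genes in place of features, 613 with the 1.5-fold limit, 359 with NM features only, 644 in the fit of 11 arrays and 0 as filed, and its lists became 6 without the dimmest 30%. Of the 348 genes 33.6% were higher and of the 359 NM features 35.9%, against 601 of 1123. Day 4 gave 1 feature with the trend and robust prior and 14 lists as filed, and the average of days 4 and 10 gave 18 lists as filed. The average over 3 days is another quantity, on 10097 features, and in the fit of 11 arrays it gave 59 features and 0 lists, with 80 features in the test across 3 days.

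Scores moved to -0.0339 at day 4 and -0.0475 at day 10 with quantile normalisation, to -0.0291 and -0.0334 without the dimmest 30%, and at day 10 to -0.0156 with only changed features. The averaged score was -0.0299 with only changed features (exact permutation p = 0.676), and with a Pearson correlation in place of the slope the exact permutation p was 0.0556. With the replicate number as a block the control change gave 729 features and changed no other count of calls by over 1.5 times. Replicate differences correlated between groups at -0.226 to 0.187. This gave no sign that the numbers pair the arrays, but with 1 difference per group it cannot exclude pairing. Feature and list tests that leave out day 21 arrays, or use blocks or weights there, could not be run with 1 control array, and the averaged and difference comparisons use all 8 arrays, so only compared groups gives no other fit. Background signal was not used here, so how far dim features lay above it is unknown.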

Other observations

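The test of lists over other groupings of the arrays was planned, and the per-array values here were picked after the result was seen.

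The conducting airway list (secretory and ciliated cell genes, 12 measured) varied between pools of 1 group. Its deviation was 0.61 on IUGR day 4 replicate 2 and 0.31 on replicate 1, against 0.12 and 0.02 in controls, and the IUGR difference of 0.39 did not pass (adjusted p = 0.117). At day 10 the values were 0.05 and -0.48 in IUGR and -0.54 and -0.09 in controls. B lymphocyte genes, with only 4 measured and not tested, stood at 0.44 and 0.18 in the day 4 controls and 0.06 and 0.00 in IUGR. T lymphocyte genes differed by 0.15 at day 4 and -0.12 at day 10, neither past the threshold. Imprinted growth genes had a mean of -0.43 for day 10 minus day 4 in controls, which did not pass (adjusted p = 0.0530).

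The IUGR differences of days 4 and 10 correlated across 10097 features at 0.220 (0.145 over all 26208), those of days 4 and 21 at 0.0215 and those of days 10 and 21 at -0.109. These are correlations across features, which are not independent replicates. IUGR replicate 2 was high in heart and brown fat genes at both day 4 and day 10. The differences between IUGR replicates of day 4 and of day 10 themselves correlated at 0.187. The correlation without these pools was not computed, so a shared diet effect cannot be read from it.

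Regrouping the 8 arrays of days 4 and 10 within days gave 18 splits, too few for a share under 0.05. For lists, the real split gave 11 and the highest other split 15, and 7 of the 18 splits gave as many or more, the real one included. The number of lists was therefore not unusual among the splits. For features, the real split and the highest other split gave 0, so all 18 gave as many.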
